A study of Homo sapiens with 42 samples.

How the data were processed

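The deposited values are FPKM per gene for 42 polyadenylated RNA libraries, in 14 groups of 3. The submitters' processing notes name HISAT2 2.0.4, Cufflinks 2.2.1 and Cuffnorm and the genome build hg19, and give these tools no order. What filters or normalization setting the authors used to make the FPKM is not given in the sources used here. A library kit described as stranded is named in the labels' protocols. The groups were taken from the treatment and cell line labels: HAP1 WT and HAP1 with CDK7 C312S, each with DMSO, YKL 500 nM, YKL 2 µM, THZ531, THZ1 or a combination at 500 nM or 2 µM of YKL, for 24 h. The treatment label of a combination names no compound, and the table's column names for it hold both the number of THZ531 and the code used for the YKL columns. The dose of THZ531 and THZ1 is not stated in the labels. Each column was matched to its sample through the sample's description, and 0 columns were left unmatched.

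The table has 26320 rows, of which 92 are ERCC spike-in RNAs (23 over 1 FPKM in all libraries) and 26228 are genes. Counts of reads are not part of it, so the depth per library is unknown, no count model was used, and intervals cover the spread between libraries only. Exact 0s in such a table can be failed estimates, since genes used in every cell are listed at 0 in single libraries (EEF1A1 in WT THZ531 replicate 2). All 12816 genes with at least 1 FPKM in at least 3 libraries were tested. Among them were 211 of 2247 short RNA rows (microRNA, small nucleolar RNA and similar), which poly(A) selection is not made to capture. These rows took 9 of the 12 largest changes with YKL 500 nM, 10 with YKL 2 µM, 3 with THZ531 and 11 with THZ1 in WT. Symbols were used as the table gives them. Genes with near-identical copies (histone and ribosomal protein genes) and overlapping or read-through genes are uncertain, since how the authors split such reads is not given.

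Differences were tested with limma 3.58.1 in R 4.3.3 (data.table, version 1.17.8) on log2(FPKM + 1): 14 group means fitted over all 42 libraries, which share 1 estimate of the spread, moderated with a trend on expression, and Benjamini-Hochberg adjusted p under 0.05 within each comparison. Log2 changes are on this scale, which understates the change of low genes, and a change of at least 2-fold is an absolute value of at least 1 on it. Errors of group means are SD over 3 libraries, and intervals of changes are 95%. Planned were 30 comparisons, and 4 were chosen after the data had been seen: the difference between lines in the effect of adding YKL to THZ531, and the departure of each WT combination from the sum of its parts. The groups were also compared for the spike-in level over the gene level, each the median log2 ratio to the geometric mean library, with exact permutation tests. The gene level uses the 10376 genes above 1 FPKM in all libraries. Across genes, the lowest correlation between libraries of 1 group was 0.97, and 0 pairs held identical values. Python 3.11.15 with matplotlib 3.10.9 drew the plots.

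Before the data were examined, 20 gene lists were fixed: S phase and E2F target genes, G2 and mitosis genes, p53 target genes, DNA repair genes reported to depend on CDK12, immediate early genes, BCL2 family and other cell death genes, integrated stress response genes, heat shock genes, NRF2 target genes, interferon response genes, NF-kB target and cytokine genes, cholesterol synthesis genes, polyadenylated histone genes, cytosolic ribosomal protein genes, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, TFIIH and CDK-activating kinase genes, other transcriptional kinase and elongation genes, blood cell genes, and epithelial and fibroblast genes, the last 2 as markers of other cell types. The 19 with at least 5 tested members were compared with all other tested genes by limma's camera, with a correlation between genes preset at 0.01 and again with one estimated from the residuals, and adjusted over the lists. Calls within a list were also counted with p adjusted over the list alone.

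The genes named follow a rule fixed at the same time. For a WT treatment against DMSO these were called genes with libraries apart and a mean of at least 5 FPKM in a compared group: up to 6 largest rises and 6 largest falls, and from each list up to 2 rising and 2 falling members with the smallest p. Other comparisons allowed 4 rises, 4 falls and 2 members per list. CDK7, CDK12, CDK13, CCNE2, E2F1, CDKN1A, MYC and MCL1 were open to naming anywhere. After the data had been seen the rule was also applied without short RNA rows and rows with an exact 0, and the largest changes named come from that list. Results of 2 genes that the rule names are not reported here.

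The fit was tested on simulated data for WT YKL 500 nM against DMSO: among 12605 genes, 200 were changed, and 54% were recovered at a log2 size of 0.25, 98% at 0.5 and 100% at 1 and 2. Of 190 calls 7.37% were false, and an unchanged comparison gave 0 calls. A shift of 0.3 given to the G2 and mitosis genes was called by camera (adjusted p = 2.11e-122), with 0 of 18 other lists called. Noise was drawn independently for each gene. The simulation therefore cannot show how often lists of correlated genes are falsely called (estimated correlation 0.665 for ribosomal protein genes).

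Alternatives chosen before the data were examined were a pseudocount of 0.1 FPKM, no filter on low values, scaling by the median ratio of genes, by total FPKM and by the spike-ins, only the groups compared, the replicate number as a block, leaving out each library in turn, and the estimated correlation for lists. Chosen after were fits without short RNA rows, without the C312S DMSO and THZ1 libraries, and with each library's trend on GC content and log2 transcript length removed. GC content and length came from the GENCODE transcripts of another build, matched by symbol for 94.7% of tested genes, and no coordinates were used. Other splits of the libraries were counted, all 10 for comparisons of 3 with 3 and 100 drawn for differences of effects. Scalings were applied before 1 FPKM was added for the logarithm. A factor per library moves all its genes alike on a log scale. List medians against the median gene therefore move under a scaling only through this addition.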

Results

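Polyadenylated RNA was sequenced from HAP1 cells, a near-haploid line derived from a chronic myeloid leukaemia, and from HAP1 cells with the C312S substitution in CDK7. CDK7 is the kinase of the CDK-activating kinase complex and of the general transcription factor TFIIH, and C312S replaces the cysteine that covalent CDK7 inhibitors bind. Both lines received DMSO, a compound whose treatment label reads YKL at 500 nM or 2 µM, THZ531 (a covalent inhibitor of CDK12 and CDK13), THZ1 (a covalent CDK7 inhibitor that also acts on CDK12 and CDK13), or THZ531 together with YKL at 500 nM or 2 µM (the combinations). YKL is taken here to be the covalent CDK7 inhibitor that the series title speaks of. Treatment lasted 24 h, and the 42 libraries form 14 groups of 3. The labels give no dose for THZ531 or THZ1. Values are FPKM as deposited, so the read depth behind each value is unknown and no counting interval can be given. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between libraries, which may be technical.

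CDK7 messenger RNA averaged 38.2 ± 2.01 FPKM in WT DMSO (SD, n = 3 here and for all group values) and between 29.1 ± 1.18 (YKL 500 nM) and 51.2 ± 2.50 (combination at 2 µM) in the treated WT groups. In C312S it was 60.5 ± 1.75 with DMSO and 75.8 ± 0.741 with THZ1, but between 31.7 ± 1.51 and 39.8 ± 1.75 in the other 5 groups. These levels do not test the substitution, which changes a codon. The C312S DMSO and THZ1 libraries also stood apart from the other C312S libraries in other measures. Their summed FPKM was 794400 ± 15200 and 852300 ± 52900, against 556800 to 591200 in the other 5 C312S groups and 456000 to 628300 in WT. On principal component 1 (24.6% of the variance) they averaged -42.7 ± 1.55 and -38.5 ± 1.18, against -19.5 to -8.02 for the other C312S groups and 38.6 ± 2.32 and 40.8 ± 2.31 for WT with YKL 500 nM and 2 µM. Across 8218 genes, which are not independent replicates, the mean change of these 5 groups against C312S DMSO rose with GC content (Spearman's rho 0.527). All 36 libraries outside the DMSO groups lay on their own line's side for at least 92.3% of 26 genes that mark the lines.

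**Figure D1:**
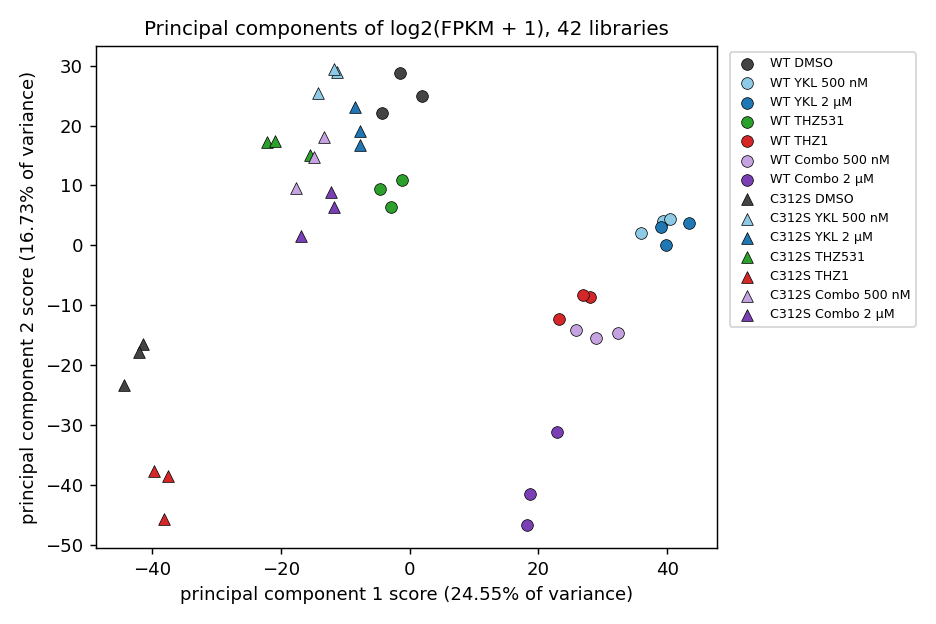
Scores of the 42 libraries on principal components 1 and 2 of log2(FPKM + 1), circles for WT and triangles for C312S, colours for treatments. The C312S DMSO and THZ1 libraries (means -42.7 and -38.5 on component 1) lie apart from the other C312S libraries, and WT libraries with YKL lie at the right (38.6 and 40.8).

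The 92 ERCC spike-in rows moved against the genes. In WT the spike-in level over the gene level was higher than in DMSO by 2.44 log2 with THZ1 (5.42-fold), 1.11 with the combination at 2 µM, 0.68 with YKL 500 nM, 0.40 with the combination at 500 nM and 0.15 with YKL 2 µM, and differed by -0.08 with THZ531. In C312S the difference was 0.22 with THZ1 and between -1.55 (THZ531) and -0.78 (combination at 2 µM) otherwise, and C312S DMSO exceeded WT DMSO by 1.37. Over these 13 comparisons the smallest two-sided exact permutation p was 0.1 (n = 3, Benjamini-Hochberg adjusted 0.118), the smallest that 3 against 3 allows. Deposited FPKM carry no such scaling, so all changes below are relative to the other genes. Scaling by spike-ins would move the median gene by -1.99 log2 in WT THZ1 against DMSO, -0.93 with the combination at 2 µM, -0.58 with YKL 500 nM, -0.34 with the combination at 500 nM, -0.10 with YKL 2 µM and 0.08 with THZ531. It would move it by 0.61 to 1.27 in C312S against DMSO, except THZ1 (-0.14). Between the DMSO groups, C312S against WT, the spike-ins would move it by -1.12 and total FPKM by -0.36. Scaling to equal total FPKM would move it by 0.20 and 0.25 in WT with YKL 500 nM and 2 µM, 0.14 with the combination at 500 nM, -0.15 with THZ1, and 0.31 to 0.36 in C312S outside THZ1.

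**Figure D2:**
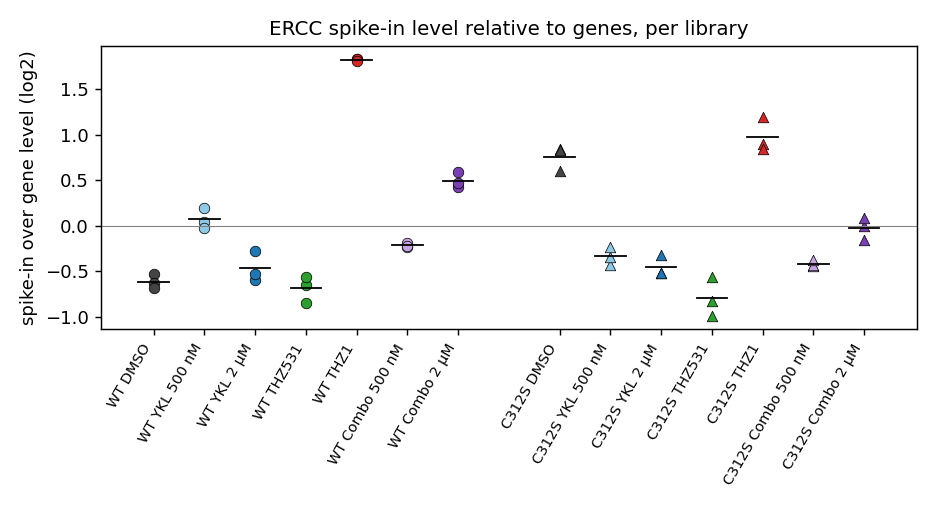
Spike-in level over gene level (log2 median ratio to the geometric mean library) per library, with a line at each group mean, circles for WT and triangles for C312S. The 3 WT THZ1 libraries average 1.82 and the WT DMSO libraries -0.62, and C312S DMSO averages 0.76.

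YKL 500 nM in WT cells lowered cell cycle genes and raised polyadenylated histone transcripts. MCM6 and MCM7, subunits of the replicative helicase, fell by 1.18 and 1.08 log2, from 113 ± 3.13 to 49.0 ± 0.189 FPKM and from 225 ± 5.84 to 106 ± 3.56 FPKM. TOP2A, the topoisomerase of dividing cells, and CDC20, an activator of the anaphase-promoting complex, fell by 1.14 and 0.86. Of the S phase and E2F target genes 37 of 44 fell and 3 rose (the same numbers adjusted over the list alone, median -0.52, camera adjusted p = 3.42e-13, adjusted p = 0.000919 with an estimated correlation). E2F1, a transcription factor of S phase entry, fell from 25.6 ± 0.468 to 14.2 ± 1.41 FPKM, while CCNE1 and CCNE2, the cyclins E, rose by 0.28 and 0.25 (-0.35 and -0.38 with spike-in scaling). Of the G2 and mitosis genes 36 of 40 fell and none rose (the same adjusted over the list alone, median -0.46, camera adjusted p = 8.26e-13, adjusted p = 0.00911 with an estimated correlation).

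Polyadenylated histone genes rose in 22 of 26 cases and fell in 2 (the same adjusted over the list alone, median 1.35, camera adjusted p = 1.45e-08, adjusted p = 0.000118 with an estimated correlation). HIST1H2BK went from 18.7 ± 1.74 to 178 ± 3.08 FPKM and HIST1H2AC from 2.22 ± 0.664 to 37.7 ± 1.70. These families hold near-identical copies, so single members are uncertain. The cell cycle inhibitor CDKN1A rose from 3.72 ± 0.351 to 13.6 ± 0.869 FPKM (1.63 ± 0.10 log2, SE), and BTG2, an antiproliferative p53 target, by 1.46. Of the p53 target genes 13 of 24 rose and 4 fell (13 and 5 adjusted over the list alone, median 0.30, camera adjusted p = 0.00497), but the list did not pass with an estimated correlation (adjusted p = 0.13 with an estimated correlation). MDM2, itself a p53 target, fell by 0.39. Integrated stress response genes fell in 23 of 27 cases and rose in 4 (the same adjusted over the list alone, median -0.56, camera adjusted p = 3.83e-08, adjusted p = 0.0112 with an estimated correlation). Its transcription factor ATF4 fell from 391 ± 20.2 to 185 ± 3.07 FPKM, and ASNS, which makes asparagine, by 1.26. MYC fell by 0.53, and 15 of 23 cholesterol synthesis genes fell and 3 rose (the same adjusted over the list alone, median -0.24, camera adjusted p = 0.0214, adjusted p = 0.025 with an estimated correlation, but 0.23 with total-FPKM scaling). Of 74 cytosolic ribosomal protein genes 73 fell (74 adjusted over the list alone, median -0.64, camera adjusted p = 5.02e-24), and that call was lost when the correlation was estimated (adjusted p = 0.167 with an estimated correlation). RPL22L1, a ribosomal protein paralog, fell from 81.6 ± 8.69 to 13.2 ± 1.35 FPKM, SNHG12, a host of small nucleolar RNAs, from 33.9 ± 1.03 to 4.74 ± 0.371, and HNRNPA1, a splicing regulator, from 493 ± 29.6 to 109 ± 3.74. POLR2A, the large subunit of RNA polymerase II, rose by 1.03, CDK7 and CDK12 fell by 0.38 and 0.33 (CDK12 -0.10 with total-FPKM scaling, limma adjusted p = 0.253). MCL1 did not pass (-0.06, 95% interval -0.16 to 0.04, but 0.17 with total-FPKM scaling, limma adjusted p = 0.0191, and -0.71 with spike-in scaling, 1.05e-06). In all 8074 of 12816 genes passed (limma, adjusted p under 0.05). Higher genes made up 49.7% of the calls, against 77.1% with total-FPKM scaling and 5.2% with spike-in scaling.

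At 2 µM YKL gave 8375 called genes in WT. MCM6 fell by 1.34, the ribonucleotide reductase subunit RRM2 from 187 ± 7.29 to 87.2 ± 0.655 FPKM, and the mitotic kinesin KIF20A from 65.2 ± 2.33 to 27.1 ± 1.03. ATF4 fell by 1.33, MYC by 0.69 and E2F1 by 0.91, while BTG2 rose by 1.66, CDKN1A by 1.42 and HIST1H2BK by 3.35. In the S phase and E2F target list 41 of 44 genes fell and 3 rose (the same adjusted over the list alone, median -0.68, adjusted p = 0.000145 with an estimated correlation). G2 and mitosis genes fell in 38 of 40 cases (39 adjusted over the list alone, median -0.72, adjusted p = 0.00115 with an estimated correlation), and 21 of 26 polyadenylated histone genes rose (21 adjusted over the list alone, median 1.43, adjusted p = 0.000138 with an estimated correlation). Among these calls 48.7% were higher, against 78.5% with total-FPKM scaling and 35% with spike-in scaling. Between the doses, 792 genes differed (274 higher and 518 lower at 2 µM). KIF20A was lower at 2 µM by a further 0.59 log2, RRM2 by 0.32 and CDCA8, of the chromosomal passenger complex, by 0.42 (with spike-in scaling 0.22 and 0.12 for RRM2 and CDCA8, and -0.061 for KIF20A, limma adjusted p = 0.587). G2 and mitosis genes fell further in 29 of 40 cases (33 adjusted over the list alone, median -0.27) and S phase and E2F target genes in 21 of 44 (32 adjusted over the list alone, median -0.17), each with adjusted p = 1.7e-05 with an estimated correlation, the latter not called with spike-in scaling (limma's camera adjusted p = 0.0768). CDKN1A (-0.21, 95% interval -0.41 to -0.01, limma adjusted p = 0.208), MYC (-0.16, adjusted p = 0.0765) and E2F1 (-0.09, adjusted p = 0.49) did not pass between the doses, and with spike-in scaling lay at 0.30, 0.38 and 0.42, above 500 nM. Without YKL 2 µM replicate 2 MYC passed (-0.20, limma adjusted p = 0.0391), and with GC and length trends removed it lay at the threshold (-0.13, adjusted p = 0.05). Of these differences 34.6% were higher at 2 µM, against 66.4% with total-FPKM scaling and 99.9% of 11504 with spike-in scaling. Leaving out WT YKL 500 nM replicates 1 and 2 left 360 and 436 genes, and leaving out WT YKL 2 µM replicates 1 and 3 left 395 and 426.

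**Figure D3:**
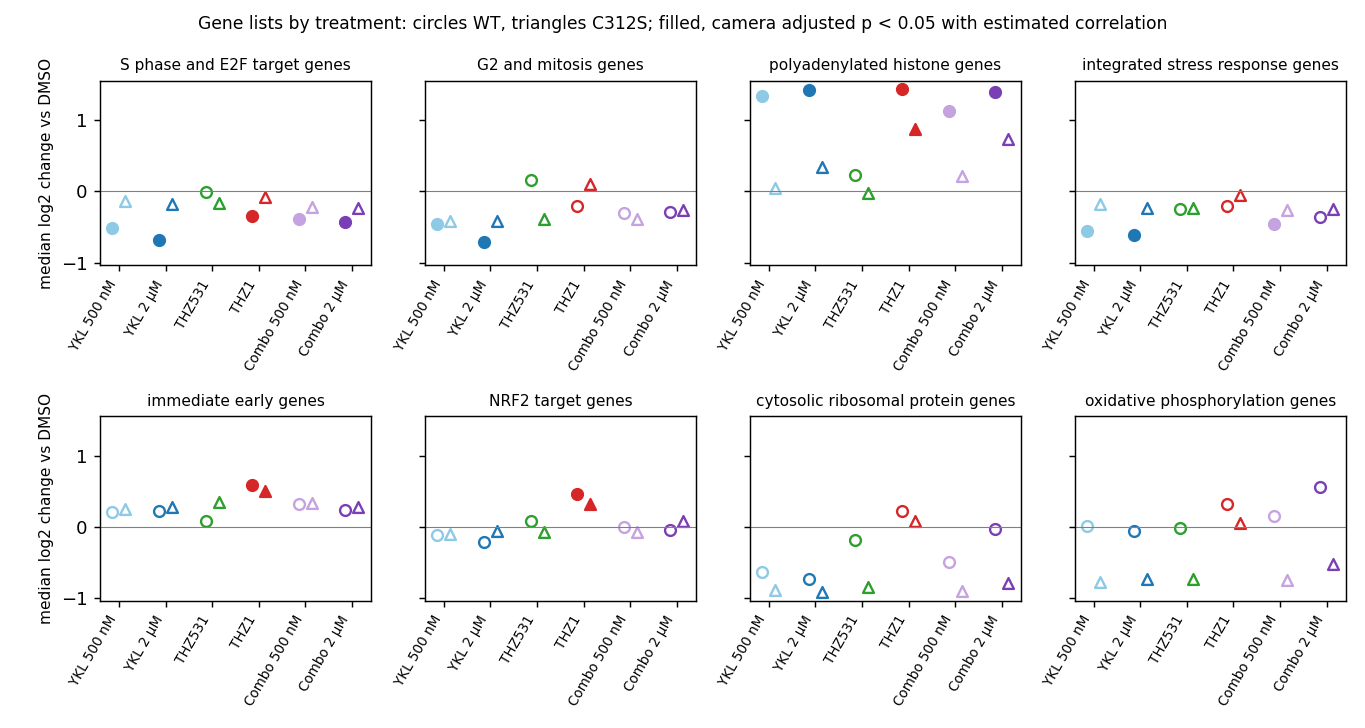
Median log2(FPKM + 1) change against DMSO of 8 gene lists for each treatment, circles for WT and triangles for C312S, filled where camera with an estimated correlation gave an adjusted p under 0.05. In WT the S phase and E2F target genes lie at -0.52 and -0.68 with YKL 500 nM and 2 µM and the histone genes at 1.35 and 1.43, and C312S points outside THZ1 are measured against the DMSO libraries that stood apart.

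THZ531 alone changed 6006 genes in WT (3309 with spike-in scaling). The polyadenylated histone transcripts HIST1H2AC and HIST1H2BK rose from 2.22 ± 0.664 to 13.0 ± 1.06 FPKM and from 18.7 ± 1.74 to 57.9 ± 6.96 FPKM. Histone genes rose in 9 of 26 cases and fell in 2 (the same adjusted over the list alone, median 0.24, camera adjusted p = 0.0121), a call not held when the correlation was estimated (adjusted p = 0.0698 with an estimated correlation) or with total-FPKM scaling (0.0907). Among DNA repair genes reported to depend on CDK12, FANCA of the Fanconi anaemia core complex rose by 0.73 and NBN by 0.38, and BRCA1 fell from 17.2 ± 0.760 to 12.3 ± 0.390 FPKM and FANCF by 0.53. The list had 12 of 32 members higher and 7 lower (the same adjusted over the list alone, median 0.06, limma's camera adjusted p = 0.48). Integrated stress response genes fell in 21 of 27 cases and rose in 1 (22 and 1 adjusted over the list alone, median -0.25, camera adjusted p = 9.78e-07, adjusted p = 0.0683 with an estimated correlation). ATF4 and the alanyl-tRNA synthetase AARS fell by 0.46 and 0.40. CDK12 and CDK13 rose by 0.43 and 0.29, HEXIM1, which holds the kinase P-TEFb inactive, by 0.53, and NELFE, of the negative elongation factor, fell by 0.91. UCP2, a mitochondrial carrier, fell from 16.2 ± 1.53 to 5.02 ± 0.120 FPKM. G2 and mitosis genes rose in 22 of 40 cases and fell in 5 (23 and 5 adjusted over the list alone, median 0.17, camera adjusted p = 0.0121, adjusted p = 0.447 with an estimated correlation, and median 0.046 and adjusted p = 0.193 with GC and length trends removed). KIF4A was higher by 0.34 and CDC20 lower by 0.58. CDKN1A (-0.23, limma adjusted p = 0.0536, 0.0217 or 0.0421 without THZ531 replicate 2 or DMSO replicate 3, 0.0492 with median-ratio scaling and 0.038 with a pseudocount of 0.1) did not pass. Nor did MYC (0.03, 95% interval -0.08 to 0.14, but 0.20 with GC and length trends removed, limma adjusted p = 0.00021) and CCNE2 (0.02, 95% interval -0.14 to 0.18). Higher calls made up 51.2%, against 65.5% with total-FPKM scaling, and the change fell with GC content across genes (Spearman's rho -0.52).

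THZ1 in WT raised immediate early, NRF2 target and histone genes and lowered S phase genes. CTGF, a secreted matrix protein and YAP target, went from 16.1 ± 0.0999 to 72.0 ± 2.27 FPKM and the transcription factor KLF10 from 5.14 ± 0.150 to 18.8 ± 0.628. Of the immediate early genes 26 of 32 rose and 2 fell (the same adjusted over the list alone, median 0.59, camera adjusted p = 1.94e-08, adjusted p = 0.00752 with an estimated correlation), MYC by 0.55. NRF2 target genes rose in 13 of 18 cases (13 adjusted over the list alone, median 0.45, camera adjusted p = 4.28e-05, adjusted p = 0.00752 with an estimated correlation, but 0.612 with spike-in scaling). Among them rose the quinone reductase NQO1 by 1.36 and ferritin light chain FTL from 634 ± 49.2 to 1300 ± 28.8 FPKM. Histone genes rose in 22 of 26 cases (22 adjusted over the list alone, median 1.43, adjusted p = 0.000435 with an estimated correlation), HIST1H2BJ by 4.08. E2F1 fell from 25.6 ± 0.468 to 10.2 ± 0.0611 FPKM and GINS1, of the replicative helicase, by 1.25, whereas the thymidylate synthase TYMS rose by 0.58. Of the S phase and E2F target genes 32 of 44 fell and 7 rose (the same adjusted over the list alone, median -0.35, camera adjusted p = 6.75e-06, adjusted p = 0.0322 with an estimated correlation). The mitotic kinase AURKB fell from 106 ± 3.14 to 32.3 ± 2.82 FPKM, and 22 of 40 G2 and mitosis genes fell and 8 rose (23 and 8 adjusted over the list alone, median -0.21, camera adjusted p = 0.008, adjusted p = 0.448 with an estimated correlation). CDKN1A rose by 1.65, HEXIM1 by 1.52, POLR2A by 1.79, BRCA1 fell by 0.98 and FANCA rose by 0.81.

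Of the DNA repair genes reported to depend on CDK12, 16 of 32 fell with THZ1 in WT and 4 rose (the same adjusted over the list alone, median -0.16, camera adjusted p = 0.0291, adjusted p = 0.448 with an estimated correlation, 0.0556 without DMSO replicate 3, 0.0915 with spike-in scaling and 0.0502 with only the groups compared). Nuclear oxidative phosphorylation genes rose in 36 of 50 cases and fell in 4 (37 and 4 adjusted over the list alone, median 0.32, camera adjusted p = 2.8e-05, adjusted p = 0.448 with an estimated correlation), with ATP5B higher by 0.89. The list's median lay at -0.11 against the median gene with spike-in scaling. Of 24 other transcriptional kinase and elongation genes 15 rose and 7 fell (the same adjusted over the list alone, median 0.24, camera adjusted p = 0.0495, adjusted p = 0.0833 with an estimated correlation), with a median of -0.04 against the median gene under spike-in scaling. That call was lost without THZ1 replicate 2 or 3 or DMSO replicate 2 or 3 (limma's camera, adjusted p = 0.0626, 0.0518, 0.0556 and 0.0526), and with total-FPKM or median-ratio scaling, trends removed or only the groups compared (0.113, 0.0544, 0.0703 and 0.0931). Higher shares of the 8816 called genes were 49.4% as deposited, 32.5% with total-FPKM scaling and 0.3% with spike-in scaling. Under the latter CDKN1A (-0.45), MYC (-1.86), CTGF (-0.26), KLF10 (-0.48), NQO1 (-0.996), FTL (-1.39), HEXIM1 (-0.72), POLR2A (-0.62), TYMS (-1.84), FANCA (-1.44) and ATP5B (-1.54) were lower than in DMSO.

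The combination of THZ531 with YKL at 500 nM in WT lowered S phase and stress response genes. MCM7 fell from 225 ± 5.84 to 97.4 ± 5.18 FPKM, CDC20 by 1.06, E2F1 by 1.15 and AURKB from 106 ± 3.14 to 36.6 ± 3.62 FPKM, while CDKN1A rose by 1.48, NQO1 by 1.57 and HIST1H2BK from 18.7 ± 1.74 to 228 ± 6.98 FPKM. In total 38 of 44 S phase and E2F target genes fell and 2 rose (39 and 2 adjusted over the list alone, median -0.39, adjusted p = 0.00218 with an estimated correlation). G2 and mitosis genes fell in 29 of 40 and rose in 4 (the same adjusted over the list alone, median -0.30, camera adjusted p = 3.71e-06, adjusted p = 0.128 with an estimated correlation). Integrated stress response genes fell in 22 of 27 cases and rose in 3 (the same adjusted over the list alone, median -0.46, adjusted p = 0.0384 with an estimated correlation), ATF4 by 1.13. BRCA1 fell by 0.63, and CDK7 did not pass (-0.01, 95% interval -0.12 to 0.11, and 0.16 with total-FPKM scaling, limma adjusted p = 0.00745, but -0.39 with spike-in scaling, 0.00173, and -0.14 with GC and length trends removed, 0.00994). Of 8740 called genes 49.8% were higher, against 67.2% with total-FPKM scaling and 13.5% with spike-in scaling.

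With the combination at 2 µM in WT, 9880 genes passed, and the change fell with GC content across genes (Spearman's rho -0.48). FOXM1, a transcription factor of mitotic genes, fell from 78.8 ± 1.36 to 29.8 ± 1.83 FPKM, CCNF from 31.9 ± 0.910 to 11 ± 1.11 and E2F1 from 25.6 ± 0.468 to 8.16 ± 0.814. HIST1H2AC rose by 4.23, the stress transcription factor ATF3 from 10.2 ± 0.325 to 34.8 ± 2.80 FPKM, NQO1 by 1.97 and CCNH, the cyclin partner of CDK7, by 1.28 (0.17 with spike-in scaling, limma adjusted p = 0.0926), and MYC fell by 0.89. SCAMP4, a secretory carrier membrane protein, fell from 21.5 ± 1.90 to 2.37 ± 0.347 FPKM. S phase and E2F target genes fell in 34 of 44 cases and rose in 4 (the same adjusted over the list alone, median -0.43, adjusted p = 0.015 with an estimated correlation). Histone genes rose in 22 of 26 and fell in 1 (the same adjusted over the list alone, median 1.39, adjusted p = 0.00146 with an estimated correlation). Oxidative phosphorylation genes rose in 39 of 50 cases and fell in 5 (the same adjusted over the list alone, median 0.56, camera adjusted p = 6.22e-06, adjusted p = 0.546 with an estimated correlation), ATP5B by 0.65 (-0.48 with spike-in scaling). CDK7 rose by 0.41 (-0.68 with spike-in scaling, and 0.083 with GC and length trends removed, limma adjusted p = 0.102). A share of 50.5% were higher, against 2.6% with spike-in scaling.

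Against THZ531 alone, adding YKL in WT changed 7833 genes at 500 nM and 9424 at 2 µM. At 500 nM MCM6 fell by 0.99, TOP2A by 1.14, ATF4 by 0.67 and E2F1 by 0.68, and CDKN1A rose from 3.04 ± 0.397 to 12.2 ± 0.909 FPKM and BTG2 by 1.39. NGFR, a neurotrophin receptor, rose from 1.83 ± 0.0548 to 12.8 ± 0.508 FPKM. S phase and E2F target genes fell in 35 of 44 cases and rose in 6 (the same adjusted over the list alone, median -0.48, adjusted p = 0.00213 with an estimated correlation). Of G2 and mitosis genes 36 of 40 fell and 1 rose (the same adjusted over the list alone, median -0.47, adjusted p = 0.00924 with an estimated correlation). At 2 µM MCM4 fell by 0.80, FOXM1 by 1.33, HNRNPA1 by 2.11 and MYC by 0.92, and HIST1H2AG rose by 2.67. There 33 of 44 S phase and E2F target genes fell and 6 rose (the same adjusted over the list alone, median -0.52, adjusted p = 0.014 with an estimated correlation). Of G2 and mitosis genes 29 of 40 fell and 4 rose (the same adjusted over the list alone, median -0.47, camera adjusted p = 7.75e-07, adjusted p = 0.111 with an estimated correlation). Higher genes made up 51.5% at 500 nM, against 64.7% with total-FPKM and 9.2% with spike-in scaling, and 52.1% at 2 µM, against 2% with spike-in scaling.

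Departure of the combination from the sum of its parts was asked as combination minus THZ531 minus YKL plus DMSO, a comparison chosen after the data were seen. At 500 nM it passed for 1137 genes. Integrated stress response genes lay above the sum in 18 of 27 cases and below it in none (22 and 0 adjusted over the list alone, median 0.25, camera adjusted p = 2.86e-17, adjusted p = 0.000413 with an estimated correlation), ASNS by 0.72 and ATF4 by 0.40. Histone genes lay below it in 6 of 26 cases (6 adjusted over the list alone, median -0.23, adjusted p = 0.00149 with an estimated correlation), HIST1H2AC by 1.97 (estimate -1.97). CDKN1A (0.08, 95% interval -0.20 to 0.36) and MYC (0.03, 95% interval -0.12 to 0.19) did not pass. Leaving out WT combination 500 nM replicate 2 left 581 genes, WT DMSO replicate 1 left 596, WT YKL 500 nM replicate 2 left 688, and WT THZ531 replicates 1 and 2 left 718 and 729. Among the calls 56.9% lay above the sum, against 11.5% with total-FPKM and 96.4% with spike-in scaling. At 2 µM 6834 genes passed, with ASNS 1.20 and ATF4 0.75 above the sum (with spike-in scaling ATF4 -0.33, and ASNS 0.14, limma adjusted p = 0.367), HIST1H2AC at -1.39, 54.5% above the sum, 10.6% with total-FPKM and 0.1% with spike-in scaling. There 20 of 27 integrated stress response genes lay above it and 2 below (the same adjusted over the list alone, median 0.36, camera adjusted p = 4.52e-06, adjusted p = 0.139 with an estimated correlation).

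THZ1 was compared with the other compounds in WT, at doses the labels do not give. Against YKL 2 µM, THZ1 left TYMS at 347 ± 1.08 against 140 ± 3.83 FPKM, the mitotic kinase PLK1 at 171 ± 4.47 against 74.3 ± 4.40 and MYC at 196 ± 1.99 against 82.7 ± 5.13. FANCA was at 24 ± 0.659 against 7.84 ± 0.122 FPKM, and BTG2 was lower by 1.55 (difference -1.55). G2 and mitosis genes were higher with THZ1 in 32 of 40 cases and lower in 1 (the same adjusted over the list alone, median 0.55, adjusted p = 0.0332 with an estimated correlation). With spike-in scaling their test turned downward (median 0.22 against the median gene, limma's camera adjusted p = 0.571). NRF2 target genes were higher in 17 of 18 (17 adjusted over the list alone, median 0.56, adjusted p = 0.00332 with an estimated correlation, but 0.27 with spike-in scaling). CDKN1A differed by 0.22 (95% interval 0.02 to 0.42, -0.21 with total-FPKM and -1.84 with spike-in scaling), a call lost without THZ1 replicate 1 (limma adjusted p = 0.0602) or 2 (0.163) and without YKL replicate 1 (0.166) or 3 (0.106). It was also lost with median-ratio scaling (0.0767), no filter (0.0639) and a pseudocount of 0.1 (0.0658). E2F1 differed by -0.34. Against THZ531, THZ1 raised CDKN1A by 1.87, CTGF by 1.5, KLF10 by 1.39 and NQO1 by 1.25 and lowered E2F1 by 0.77. Immediate early genes were higher in 27 of 32 cases and lower in 2 (the same adjusted over the list alone, median 0.50, adjusted p = 0.0055 with an estimated correlation). Histone genes were higher in 22 of 26 (22 adjusted over the list alone, median 1.32, adjusted p = 0.000246 with an estimated correlation). Against YKL 2 µM, THZ531 left TOP2A at 179 ± 7.90 against 58.2 ± 2.08 FPKM, MCM6 at 111 ± 2.46 against 43.9 ± 1.86 and CDKN1A at 3.04 ± 0.397 against 11.7 ± 1.07. MCL1 did not pass there (-0.01, 95% interval -0.11 to 0.09, but -0.23 with total-FPKM scaling, limma adjusted p = 0.00227). These comparisons called 8719, 7840 and 8736 genes. The higher share was 52.1% for THZ1 against YKL (12.7% with total-FPKM and 0.1% with spike-in scaling), 49.9% for THZ1 against THZ531 (22.5% and 0.1%) and 51.5% for THZ531 against YKL (28.7% and 68.6%). With spike-in scaling TYMS (-1.01), PLK1 (-1.10), MYC (-1.06) and FANCA (-0.64) for THZ1 against YKL and CDKN1A (-0.26), CTGF (-0.93), KLF10 (-0.86) and NQO1 (-1.17) for THZ1 against THZ531 changed sign.

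The combination at 500 nM and THZ1 differed in WT in NRF2 target genes. IER3, an immediate early gene, was at 7.17 ± 0.719 FPKM with the combination at 500 nM and 6.71 ± 1.20 at 2 µM, against 32.4 ± 2.47 with THZ1. Immediate early genes were lower in 22 of 32 cases at 500 nM and 24 at 2 µM and higher in 5 and 3 (the same adjusted over the list alone, medians -0.48 and -0.52, camera adjusted p = 3.11e-05 and 0.000492), calls lost when the correlation was estimated (adjusted p = 0.08 and 0.194 with an estimated correlation). MYC was lower than with THZ1 by 1.02 at 500 nM and 1.44 at 2 µM (differences -1.02 and -1.44), and the pentose phosphate enzyme TKT lay at 208 ± 9.41 FPKM at 500 nM against 390 ± 13.4. NRF2 target genes were lower in 16 of 18 cases at 500 nM and higher in 1 (17 and 1 adjusted over the list alone, median -0.44, adjusted p = 0.00404 with an estimated correlation, but 0.424 with spike-in scaling). At 2 µM they were lower in 11 and higher in 3 (the same adjusted over the list alone, median -0.35, camera adjusted p = 0.0218, adjusted p = 0.194 with an estimated correlation). At 500 nM E2F1 (0.09, 95% interval -0.05 to 0.23) did not pass, but did with total-FPKM scaling (0.40, limma adjusted p = 7.82e-05), spike-in scaling (1.82, 9.77e-15) and GC and length trends removed (0.26, 7.9e-05). There CDKN1A (-0.16, 95% interval -0.36 to 0.04, 0.15 with total-FPKM and 1.64 with spike-in scaling) did not pass. At 2 µM CDKN1A (-0.53) and FOXM1 (-1.20) were lower and CCNE2 was higher, at 24.4 ± 2.70 against 10.8 ± 0.653 FPKM. Called genes numbered 7924 at 500 nM (51.7% higher, 86.8% with total-FPKM and 100% with spike-in scaling) and 9478 at 2 µM (51.9% higher, 99.5% with spike-in scaling). With spike-in scaling MYC (1.00) and TKT (1.13) at 500 nM and CDKN1A (0.61) and FOXM1 (0.08) at 2 µM changed sign, and IER3 at 500 nM (-0.12, limma adjusted p = 0.375) and MYC at 2 µM (-0.14, 0.272) lost the call.

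The lines' DMSO groups differed in 10148 genes, the C312S split included. GTSF1, a germ cell small RNA pathway gene, was at 296 ± 13.4 FPKM in C312S and 0.596 ± 0.285 in WT, and the myomesin MYOM1 at 7.74 ± 0.35 and 0.178 ± 0.00569. THY1, a cell surface glycoprotein, was at 1.14 ± 0.258 in C312S against 16.6 ± 0.589, and TRIM5, an antiretroviral factor, at 0.704 ± 0.110 against 12.3 ± 0.333. CCNE2 was higher by 1.49 (0.092 with spike-in scaling, limma adjusted p = 0.48) and MYC lower (-0.85). CDKN1A did not pass (-0.07, 95% interval -0.27 to 0.12, but 0.28 with GC and length trends removed, limma adjusted p = 0.00883, and -0.46 with total-FPKM, 6.66e-05, and -1.18 with spike-in scaling, 8.17e-10). Cytosolic ribosomal protein genes were higher in 71 of 74 cases (71 adjusted over the list alone, median 0.90, camera adjusted p = 1.48e-15, adjusted p = 0.429 with an estimated correlation). Oxidative phosphorylation genes were higher in 43 of 50 and lower in 5 (the same adjusted over the list alone, median 0.83, camera adjusted p = 2.18e-09, adjusted p = 0.429 with an estimated correlation). These lists moved with that split, and the difference fell with GC content (Spearman's rho -0.55). Higher genes in C312S made up 52.1%, against 21.8% with total-FPKM and 0.4% with spike-in scaling.

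THZ1 was the treatment whose C312S libraries lay with their DMSO libraries, and there it changed 8149 genes. HIST1H2BK rose from 20 ± 0.867 to 161 ± 11.4 FPKM and histone genes in 17 of 26 cases (17 adjusted over the list alone, median 0.87, adjusted p = 0.00965 with an estimated correlation). MYC rose from 73.9 ± 2.17 to 164 ± 7.98 FPKM, CTGF from 5.98 ± 0.719 to 19.2 ± 1.23 and HEXIM1 from 4.15 ± 0.210 to 13.6 ± 0.344. In all 25 of 32 immediate early genes rose and 2 fell (26 and 2 adjusted over the list alone, median 0.51, adjusted p = 0.0159 with an estimated correlation). NRF2 target genes rose in 16 of 18 cases (16 adjusted over the list alone, median 0.32, adjusted p = 0.0129 with an estimated correlation), FTL by 0.93. Cholesterol synthesis genes rose in 13 of 23 and fell in 3 (the same adjusted over the list alone, median 0.34, adjusted p = 0.0159 with an estimated correlation), the squalene epoxidase SQLE by 0.79. FANCA rose by 1.31, and BRCA1 fell by 0.89 and E2F1 by 0.65. CDKN1A fell by 0.22 (limma adjusted p = 0.0471), a call lost without THZ1 replicate 1 or 2 (-0.21, limma adjusted p = 0.107, and -0.18, 0.153) and without DMSO replicate 1 or 2 (-0.13, 0.292, and -0.21, 0.0956). It was also lost with spike-in scaling (0.0587), GC and length trends removed (-0.096, limma adjusted p = 0.37), no filter (0.0724) and only the groups compared (0.135). Among S phase and E2F target genes 20 of 44 fell and 11 rose (the same adjusted over the list alone, median -0.08, camera adjusted p = 0.0209, adjusted p = 0.33 with an estimated correlation). Rising genes made up 53.2%, against 40.3% with total-FPKM and 19.7% of 5047 with spike-in scaling.

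**Figure D4:**
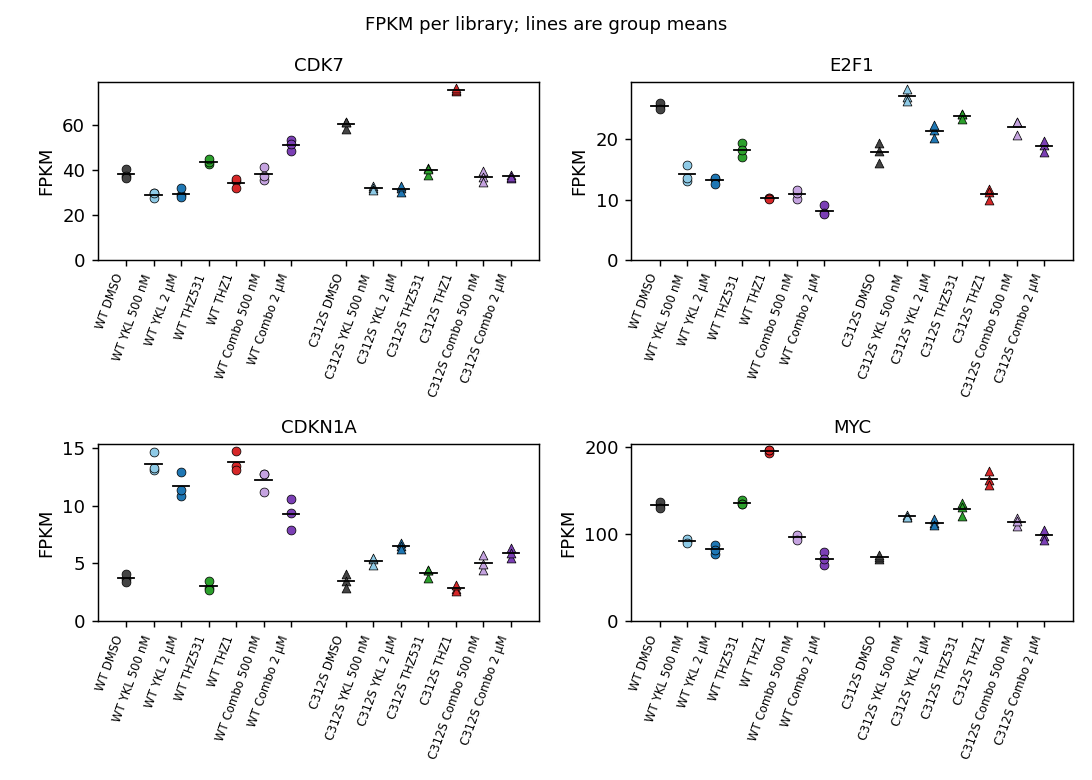
FPKM of CDK7, E2F1, CDKN1A and MYC in each library, with a line at each group mean, circles for WT and triangles for C312S. In WT, CDKN1A averages 3.72 with DMSO and 13.6, 11.7, 13.8, 12.2 and 9.29 with YKL 500 nM, YKL 2 µM, THZ1 and the combinations at 500 nM and 2 µM, and in C312S no group mean exceeds 6.5.

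The other 5 C312S treatments were measured against DMSO libraries that stood apart, and their changes shared this split. YKL 500 nM, YKL 2 µM, THZ531 and the combinations at 500 nM and 2 µM called 9795, 9715, 9494, 9412 and 8808 genes. Cytosolic ribosomal protein genes fell in 71, 73, 72, 73 and 73 of 74 cases (the same adjusted over the list alone, medians -0.89, -0.92, -0.84, -0.90 and -0.79, adjusted p = 0.52, 0.397, 0.444, 0.301 and 0.254 with an estimated correlation). CDK7 fell by 0.89, 0.91, 0.59, 0.69 and 0.69 in that order (0.25, 0.34, 1.00, 0.52 and 0.14 with spike-in scaling). MYC rose by 0.70 with YKL 500 nM and 0.61 with YKL 2 µM, where CDKN1A rose from 3.50 ± 0.597 to 5.25 ± 0.317 and 6.5 ± 0.252 FPKM (at 500 nM 0.16 log2 with GC and length trends removed, limma adjusted p = 0.124). The filamin FLNA rose with YKL 500 nM from 48.6 ± 3.62 to 149 ± 4.27 FPKM. HIST1H2AC rose by 1.68 with YKL 2 µM, 1.58 with the combination at 500 nM and 2.59 with that at 2 µM. Histone genes rose in 16 of 26 cases with the combination at 2 µM and fell in 2 (the same adjusted over the list alone, median 0.73, camera adjusted p = 0.00352, adjusted p = 0.0721 with an estimated correlation, and 0.61 with total-FPKM scaling). With spike-in scaling their median was 0.38 against the median gene, and the test changed sign. With THZ531 FANCA rose by 0.78. The changes rose with GC content across genes in all 5 (Spearman's rho 0.58, 0.56, 0.45, 0.47 and 0.52), against -0.10 for THZ1. Higher shares in that order were 48.2%, 48.3%, 46.7%, 47.7% and 47.7%, against 79.8%, 80.8%, 81.1%, 84.6% and 84.4% with total-FPKM scaling and 99.9%, 99.8%, 100%, 100% and 99.3% with spike-in scaling.

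Comparisons inside this set of C312S libraries do not use the DMSO libraries. Adding YKL 500 nM to THZ531 in C312S called 74 genes, among them HIST1H2AC, which rose from 5.74 ± 0.336 to 17.2 ± 2.19 FPKM. HIST1H2BK rose by 0.68, the smooth muscle actin ACTG2 by 0.61, and HNRNPA1 fell by 0.29, a call lost without combination replicate 3 (limma adjusted p = 0.0566) or THZ531 replicate 2 (0.0773). With only the groups compared HIST1H2BK (limma adjusted p = 0.281), ACTG2 (0.238) and HNRNPA1 (0.697) lost the call, and ACTG2 with spike-in scaling (0.26, 0.0528). Histone genes rose in 5 of 26 cases (10 adjusted over the list alone, median 0.38, camera adjusted p = 3.25e-17, adjusted p = 1.14e-07 with an estimated correlation). CDKN1A (0.21, 95% interval 0.01 to 0.41, limma adjusted p = 0.522, and -0.11 with spike-in scaling), E2F1 (-0.11, 95% interval -0.25 to 0.03) and MYC (-0.17, adjusted p = 0.186) did not pass. With spike-in scaling E2F1 (-0.48, limma adjusted p = 0.00448) and MYC (-0.55, 0.00231) did, and MYC also with GC and length trends removed (-0.17, 0.0378). Leaving out single libraries left 28 (without THZ531 replicate 2), 33 (THZ531 replicate 1), 33 (combination replicate 3), 40 (combination replicate 2) and 45 genes (THZ531 replicate 3), and a fit of these groups alone called 8. A share of 67.6% were higher, against 90.6% of 117 with total-FPKM and 0.2% of 10091 with spike-in scaling.

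At 2 µM the addition to THZ531 in C312S called 4465 genes. HIST1H2AC rose from 5.74 ± 0.336 to 35.6 ± 3.42 FPKM, HIST1H2BK from 25.6 ± 2.39 to 69.2 ± 5.12 and the smooth muscle gene TAGLN from 2.07 ± 0.158 to 9.01 ± 1.22. NEAT1, a nuclear long noncoding RNA, fell from 16.2 ± 1.73 to 8.44 ± 0.544 FPKM, MYC by 0.39 and E2F1 by 0.33, and CDKN1A rose by 0.41 (-0.25 with spike-in scaling). Histone genes rose in 15 of 26 cases (15 adjusted over the list alone, median 0.70, camera adjusted p = 2.19e-08, adjusted p = 7.86e-05 with an estimated correlation). Among S phase and E2F target genes 20 of 44 fell and 7 rose (21 and 8 adjusted over the list alone, median -0.09, camera adjusted p = 0.0415, adjusted p = 0.57 with an estimated correlation). That call was lost without combination replicate 1 or 2 (limma's camera, adjusted p = 0.0857 and 0.0755) or THZ531 replicate 3 (0.0866). Rising genes made up 53.1%, against 38% with total-FPKM and 0.3% of 11784 with spike-in scaling. Between YKL doses in C312S 470 genes differed. HIST1H2AC was higher at 2 µM by 1.15, HIST1H2BK by 0.76 and ACTG2 by 0.98, and E2F1 and the thymidine kinase TK1 were lower (-0.34 and -0.31, and not called with spike-in scaling, -0.23 and -0.20, limma adjusted p = 0.45 and 0.463). Histone genes were higher in 6 of 26 cases (8 adjusted over the list alone, median 0.33, camera adjusted p = 5.46e-09, adjusted p = 4.51e-05 with an estimated correlation). Of S phase and E2F target genes 12 of 44 were lower and 2 higher (22 and 3 adjusted over the list alone, median -0.09, adjusted p = 0.0404 with an estimated correlation). Leaving out YKL 500 nM replicates 1, 2 and 3 left 221, 176 and 273 genes, and leaving out YKL 2 µM replicates 1 and 2 left 246 and 262. Without YKL 2 µM replicate 3, 174 higher and 138 lower genes were left, and removing GC and length trends gave 823. Higher genes at 2 µM made up 55.1%, against 100% of 28 with spike-in scaling.

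Whether C312S changed the effect of a treatment was tested as a difference of effects, C312S minus WT. For the addition of YKL to THZ531, which needs no DMSO library and was chosen after the data were seen, 5318 genes differed at 500 nM and 6799 at 2 µM. At 500 nM MCM6 and MCM7 fell in WT by 0.99 and 0.98, and the difference of effects was 0.90 and 0.91. It was 1.09 for TOP2A, -1.5 for CDKN1A, -1.25 for BTG2, -2.31 for NGFR and -1.29 for HIST1H2BK. S phase and E2F target genes differed upward in 32 of 44 cases and downward in 4 (33 and 4 adjusted over the list alone, median 0.44, adjusted p = 0.00154 with an estimated correlation). Of G2 and mitosis genes 34 of 40 differed upward (35 adjusted over the list alone, median 0.44, adjusted p = 0.00363 with an estimated correlation). Histone genes differed downward in 13 of 26 (13 adjusted over the list alone, median -0.74, adjusted p = 0.00363 with an estimated correlation). At 2 µM FOXM1 differed by 1.18, KIF20A by 1.21, CDKN1A by -0.93 and HIST1H2BK by -0.86. There the S phase and E2F target genes differed upward in 33 of 44 cases and downward in 4 (33 and 5 adjusted over the list alone, median 0.51, adjusted p = 0.00377 with an estimated correlation). Mitotic list members differed upward in 25 of 40 and downward in 1 (26 and 1 adjusted over the list alone, median 0.53, adjusted p = 0.0257 with an estimated correlation). Histone genes differed downward in 14 of 26 (14 adjusted over the list alone, median -0.66, camera adjusted p = 0.0113, adjusted p = 0.0521 with an estimated correlation, and 0.0786 with a pseudocount of 0.1). The upward share was 49.3% at 500 nM (36.4% with total-FPKM and 59.8% of 2458 with spike-in scaling) and 48.8% at 2 µM (91.2% with spike-in scaling).

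The effect of THZ1 against DMSO differed between the lines in 5408 genes. CDKN1A rose in WT and did not in C312S, a difference of -1.86, and KLF10 (-1.05), CYR61, a matrix protein and immediate early gene (-0.87), and HIST1H2AG (-1.77) responded less in C312S. The mitotic genes BUB1B (0.76) and AURKA (0.71) and MYC (0.59) differed upward. G2 and mitosis genes differed upward in 30 of 40 cases (30 adjusted over the list alone, median 0.31, camera adjusted p = 2.42e-10, adjusted p = 0.0299 with an estimated correlation). Histone genes differed downward in 12 of 26 (12 adjusted over the list alone, median -0.62, adjusted p = 0.0299 with an estimated correlation). Among S phase and E2F target genes 21 of 44 differed upward and 6 downward (25 and 6 adjusted over the list alone, median 0.18, camera adjusted p = 0.00143, adjusted p = 0.185 with an estimated correlation). With spike-in scaling 99.9% of 12317 calls were upward, against 53.1% as deposited and 65.9% with total-FPKM scaling, and CDKN1A (0.13), KLF10 (0.89), CYR61 (1.29) and HIST1H2AG (0.07) changed sign.

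The other interactions use the C312S DMSO libraries that stood apart, and each rose with GC content across genes (Spearman's rho 0.51 to 0.64). YKL 500 nM, YKL 2 µM, THZ531 and the combinations at 500 nM and 2 µM differed between lines in 9445, 9208, 8716, 9542 and 10085 genes. The difference for HIST1H2BK was -2.97 with YKL 500 nM, -2.37 with YKL 2 µM, -2.52 with the combination at 500 nM and -2.10 at 2 µM (there -0.22 with spike-in scaling, limma adjusted p = 0.241). CDKN1A differed by -1.16 and -0.68 with YKL 500 nM and 2 µM (0.27 and 0.34 with spike-in scaling), MYC by 1.24 and 1.3, and E2F1 by 1.40 with YKL 500 nM. SCAMP4 differed by 2.25 and 2.36 with YKL and by 2.85 and 3.05 with the combinations. Histone genes differed downward in 18 and 15 of 26 cases with YKL 500 nM and 2 µM (18 and 15 adjusted over the list alone, medians -1.22 and -0.91, adjusted p = 0.0149 and 0.0448 with an estimated correlation). With the combinations at 500 nM and 2 µM 15 and 21 did (the same adjusted over the list alone, medians -0.95 and -1.10, camera adjusted p = 0.0036 and 0.0209, adjusted p = 0.0607 and 0.197 with an estimated correlation). S phase and E2F target genes differed upward in 24 and 26 of 44 and downward in 15 and 9 (24, 26, 15 and 10 adjusted over the list alone, medians 0.30 and 0.38, camera adjusted p = 0.0106 and 0.000155, adjusted p = 0.54 and 0.146 with an estimated correlation). Upward shares were 47%, 47.9%, 48.2%, 47.2% and 47.7%, against 61.7%, 59.3%, 77.1%, 65.7% and 67.7% with total-FPKM scaling and 99.1%, 97.9%, 99.8%, 98.9% and 99.5% with spike-in scaling.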

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

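Chosen only after the results were seen were the tests of the C312S library split and of the spike-ins, the test of the YKL doses on histone genes, and the comparisons for the difference between lines in the effect of adding YKL to THZ531 and for the departure from the sum. The results below stood out because a test of the difference itself put the lines apart, or because they lie in spike-in values that the gene comparisons do not use.

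The C312S DMSO and THZ1 libraries lay apart from the other C312S libraries, and every effect against C312S DMSO outside THZ1 carries this split. GC content and transcript length as the whole cause are argued against by the 64.8% of the variance over genes of the 5 groups' mean change that remained without their trends, with 116 genes at 2-fold or more (224 before) and the ribosomal protein median at -0.78 (-0.86 before). A response to THZ531 shared by the lines needs like changes in WT, where the slope on the C312S changes over genes was 0.036 (0.854 for THZ1). The C312S groups with YKL alone received no THZ531 and still lay apart from DMSO, which also argues against such a response. WT libraries or WT RNA among the other 5 groups are argued against, since the ribosomal protein genes would need a WT share of at least 0.95 and 17 genes that mark WT put it at 0.0101 or less (medians over genes). A culture or library batch that the DMSO and THZ1 libraries shared may account for the split (Spearman's rho of the mean change with GC content 0.527), but it cannot be told apart from the treatments, since the labels give no batch and the split follows the groups.

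Spike-ins were higher over the genes than in DMSO by 2.44 log2 in WT THZ1 and by 1.11 in the WT combination at 2 µM, each with all 3 libraries above all 3 DMSO libraries. Random differences in volume between single libraries are argued against by a pooled SD within groups of 0.124. Less messenger RNA per spike-in molecule in the treated cells may account for the 2.44, but cannot be told apart from a spike-in volume or RNA input that differed by group, since the labels do not say how the spike-ins were added. Untreated groups differed as well, C312S DMSO from WT DMSO by 1.37.

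Polyadenylated histone genes rose in C312S, where the cysteine that covalent CDK7 inhibitors bind is replaced, when YKL 2 µM was added to THZ531 (median 0.70, higher in 15 of 26 genes). GC and length trends are argued against, since the median was 0.73 without them (limma's camera adjusted p = 2.54e-07). An effect of YKL that does not need the replaced cysteine may account for it: it needs histone genes to rise with the YKL dose in C312S without THZ531 too, and the median there was 0.33 (adjusted p = 4.51e-05 with an estimated correlation), with HIST1H2AC higher by 1.15. Reads shared between near-identical histone copies and a change in polyadenylation were not tested, and stay open.

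Adding YKL to THZ531 moved the lists apart between the lines, at 500 nM by 0.44 for S phase and E2F target genes, 0.44 for G2 and mitosis genes and -0.74 for histone genes (medians, C312S minus WT). At 2 µM these differences were 0.51, 0.53 and -0.66, the last call lost (adjusted p = 0.0521 with an estimated correlation and 0.0786 with a pseudocount of 0.1). CDKN1A differed by -1.86 under THZ1 (0.13 with spike-in scaling), where it rose in WT from 3.72 to 13.8 FPKM (-0.45 log2 with spike-in scaling) and in C312S went from 3.50 to 2.85. Called genes for the difference between lines numbered 9445 with YKL 500 nM, and of 100 drawn splits only the real one gave as many (highest other 9332). With YKL 2 µM they numbered 9208 (again 1, highest other 7634) and with THZ531 8716 (1, 8176). The combinations gave 9542 (1, 8677) at 500 nM and 10085 (1, 8685) at 2 µM. For THZ1 12 of 100 splits, the real one included here and below, gave as many as the 5408 genes (highest other 9477). For the addition of YKL to THZ531 9 reached the 5318 at 500 nM (6385) and 11 the 6799 at 2 µM (9216). For the departure from the sum, 19 reached the 1137 genes at 500 nM (highest other 7115) and 10 the 6834 at 2 µM (8314). Of these splits 11, 8, 10, 18 and 9 kept a pair of groups whole and so carried its treatment effect. Such splits test for any effect, so no count excludes chance for a difference of effects. The 76, 81, 77, 79 and 80 splits that mixed both pairs gave at most 2, 1, 0, 1 and 1 genes.

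For comparisons of 3 with 3 libraries, 10 splits are too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many genes. Real and highest other counts against DMSO in WT were 8074 and 0 for YKL 500 nM, 8375 and 22 for YKL 2 µM, 6006 and 1 for THZ531, 8816 and 2 for THZ1, 8740 and 107 for the combination at 500 nM and 9880 and 45 at 2 µM. In C312S they were 9795 and 1, 9715 and 1, 9494 and 0, 8149 and 2, 9412 and 0, and 8808 and 1, in the same order. Between the DMSO groups they were 10148 and 1, between YKL doses 792 and 1 in WT and 470 and 1 in C312S. Combinations against THZ531 gave 7833 and 1 and 9424 and 0 in WT and 74 and 1 and 4465 and 1 in C312S. Combinations against THZ1 gave 7924 and 3 and 9478 and 1986, THZ1 against THZ531 7840 and 1, THZ1 against YKL 2 µM 8719 and 1, and THZ531 against YKL 2 µM 8736 and 1.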

How the results depend on the processing

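The fits without short RNA rows, without the C312S DMSO and THZ1 libraries and with GC and length trends removed were chosen only after the results were seen, and the others before the data were examined. All 34 counts of called genes stayed within 1.5 times with a pseudocount of 0.1 FPKM, no filter, median-ratio scaling and no short RNA rows, and so did the 21 that could be made without the C312S DMSO and THZ1 libraries. Counts of at least 2-fold moved by more than 1.5 times in 32 of 34 cases with the pseudocount of 0.1, where changes of low genes are less reduced. They moved in 28 cases with spike-in scaling, 13 with GC and length trends removed, 12 with total-FPKM scaling, 2 without short RNA rows and 1 with only the groups compared, the difference between lines for THZ531 from 568 to 105 with trends removed and WT THZ1 from 551 to 11432 with spike-in scaling, so the report gives none. An estimated correlation lost 129 of 187 list calls, spike-in scaling 36 (29 others reversed) and removing GC and length trends 15 (1 other). Total-FPKM scaling lost 27, only the groups compared 13, the smaller pseudocount 5, median-ratio scaling 3 and no filter 0. Of 225 named gene values 11, 1 and 1 lost their call with spike-in, total-FPKM and median-ratio scaling, 6, 3 and 1 gained one, and 52, 6 and 1 changed sign. Without read counts in the table, what depth limits cannot be computed, and spread between libraries is the only error given.

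Counts moved most with spike-in scaling: WT THZ531 from 6006 to 3309, C312S THZ1 from 8149 to 5047, C312S minus WT for THZ1 from 5408 to 12317, and YKL 2 µM against 500 nM from 792 to 11504 in WT and from 470 to 28 in C312S. The combinations against THZ531 in C312S went from 74 to 10091 at 500 nM and from 4465 to 11784 at 2 µM, and the difference between lines at 500 nM from 5318 to 2458. In WT the combination at 500 nM against THZ1 went from 7924 to 12442, THZ1 against THZ531 from 7840 to 12459, and the departures from the sum from 1137 to 439 at 500 nM and from 6834 to 11593 at 2 µM. Total-FPKM scaling moved the C312S combination at 500 nM against THZ531 to 117 and the departure at 500 nM to 1957. Removing GC and length trends moved the former to 154 and YKL 2 µM against 500 nM in C312S to 823. Fits of only the groups compared, with fewer libraries behind the spread, gave 409 genes between the WT doses, 8 for the C312S combination at 500 nM against THZ531 and 646 for the departure at 500 nM. The cause was not tested for the scalings or the trends.

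Leaving out each library in turn gave 264 counts, of which 20 moved by more than 1.5 times, as did 8 of 264 counts of at least 2-fold. They ranged from 360 to 662 genes between the WT doses, from 176 to 3.1e+02 (174 higher and 138 lower) between the C312S doses, from 28 to 63 for the C312S combination at 500 nM against THZ531 and from 581 to 1196 for the departure at 500 nM. Among 1416 list tests 37 lost the call, and among 1584 gene values 10 lost it, 3 gained it and 5 changed sign, all 5 in genes that did not pass: CDK7 with the WT combination at 500 nM (-0.068 to 0.044), CDKN1A between the DMSO groups (-0.17 to 0.025) and MCL1 for WT THZ531 against YKL 2 µM (-0.026 to 0.003). Each such fit has 1 library fewer, and the cause was not tested further.

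Replicate numbers were fitted as a block, although same-numbered libraries deviated together with a mean r of only 0.012 in WT and -0.006 in C312S, and 8 of 21 and 3 of 21 libraries lay closest to their own number, so the numbers do not pair the samples. With the block 8140 genes were called for WT YKL 500 nM (8074 without), 842 between the WT doses (792) and 550 between the C312S doses (470), and no count moved by over 1.5 times. The calls that changed were CDKN1A in WT THZ531 (-0.23, limma adjusted p = 0.0461), the other transcriptional kinase and elongation list in WT THZ1 (0.25, limma's camera adjusted p = 0.0536) and the S phase and E2F target list for the WT combination at 2 µM against THZ1 (-0.29, adjusted p = 0.0523).

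Gene values changed sign with spike-in scaling in WT against DMSO for CCNE1 (-0.35) and CCNE2 (-0.38) with YKL 500 nM and for ATP5B (-0.48) and CDK7 (-0.68) with the combination at 2 µM. With THZ1 they did for CTGF (-0.26), KLF10 (-0.48), MYC (-1.86), NQO1 (-0.996), FTL (-1.39), TYMS (-1.84), CDKN1A (-0.45), FANCA (-1.44), HEXIM1 (-0.72), POLR2A (-0.62), ATP5B (-1.54), BAG3 (-1.10) and HSPH1 (-1.80). In C312S CDK7 changed sign with YKL 500 nM (0.25), YKL 2 µM (0.34), THZ531 (1.00) and the combinations (0.52 and 0.14), and CDKN1A with the combinations against THZ531 (-0.11 and -0.25). In C312S minus WT CDKN1A did with YKL 500 nM (0.27), YKL 2 µM (0.34) and THZ1 (0.13), and KLF10 (0.89), CYR61 (1.29) and HIST1H2AG (0.073) with THZ1. Between YKL doses in WT RRM2 (0.22), CDCA8 (0.12), E2F1 (0.42), CDKN1A (0.30) and MYC (0.38) did. Against THZ1 in WT these were TKT (1.13), MYC (1.00) and CDKN1A (1.64) for the combination at 500 nM and FOXM1 (0.081) and CDKN1A (0.61) for that at 2 µM. For THZ1 against THZ531 they were MYC (-1.96), CDKN1A (-0.26), KLF10 (-0.86), CTGF (-0.93) and NQO1 (-1.17), and against YKL 2 µM TYMS (-1.01), PLK1 (-1.10), MYC (-1.06), FANCA (-0.64) and CDKN1A (-1.84). MCL1 for THZ531 against YKL 2 µM (0.17) and ATF4 in the departure at 2 µM (-0.33) also changed sign. Total-FPKM scaling turned MCL1 with WT YKL 500 nM (0.17), CDK7 with the WT combination at 500 nM (0.16, and 0.003 with median-ratio scaling), CDKN1A for that combination against THZ1 (0.15) and for THZ1 against YKL 2 µM (-0.21), and CDKN1A (-0.045) and MYC (-0.11) in the departure at 500 nM. Removing GC and length trends turned CCNE2 with WT THZ531 (-0.076), CDKN1A between the DMSO groups (0.28) and the immediate early list with C312S YKL 500 nM (-0.067). The cause was not tested.

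List tests changed direction with spike-in scaling in 29 cases (medians against the median gene in brackets). With THZ1 in WT these were heat shock (-0.19), ribosomal protein (-0.22), oxidative phosphorylation (-0.11) and other transcriptional kinase genes (-0.041). With the combination at 2 µM in C312S they were S phase (-0.016) and histone genes (0.38). In C312S minus WT they were ribosomal protein genes with the combinations at 500 nM (-0.093) and 2 µM (-0.30), oxidative phosphorylation genes with THZ1 (0.10) and G2 and mitosis genes with THZ531 (-0.12). Between the WT doses the ribosomal protein (-0.006), oxidative phosphorylation (0.007) and integrated stress response genes (-0.025) turned, and for the combination at 2 µM against THZ531 in C312S the oxidative phosphorylation genes (0.11). Against THZ1 in WT the combination at 500 nM turned in ribosomal protein (-0.28), oxidative phosphorylation (0.17), S phase (0.18), integrated stress response (0.035) and cholesterol genes (0.13), and that at 2 µM in ribosomal protein (0.13) and S phase genes (-0.023). For THZ1 against THZ531 ribosomal protein (-0.040) and oxidative phosphorylation genes (-0.050) turned. For THZ1 against YKL 2 µM these were heat shock (-0.17), oxidative phosphorylation (-0.056), S phase (0.009), G2 and mitosis (0.22), integrated stress response (0.056) and cholesterol genes (-0.10). These medians moved because 1 FPKM was added after the scaling, so that low genes moved less. They are no measure of how a list depends on RNA amount. What else turned the tests was not tested.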

Other observations

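Only the fit with GC and length trends removed and the correlations between comparisons were chosen after the results were seen in this part. Heat shock genes, which carry chaperones, were higher with THZ1 in both lines. In WT 13 of 19 rose and 3 fell (the same adjusted over the list alone, median 0.20, camera adjusted p = 0.0285, adjusted p = 0.448 with an estimated correlation), but the call was lost with total-FPKM scaling (median 0.17, limma's camera adjusted p = 0.113), with GC and length trends removed (0.22, 0.0703) and without DMSO replicate 3 (0.0556), and the median lay at -0.19 against the median gene with spike-in scaling. BAG3, a cochaperone of HSP70, rose from 16.9 ± 1.04 to 40.7 ± 0.25 FPKM and HSPH1, a nucleotide exchange factor of HSP70, from 128 ± 7.11 to 195 ± 7.02 (-1.10 and -1.80 log2 with spike-in scaling). In C312S 15 rose and 2 fell (the same adjusted over the list alone, median 0.40, camera adjusted p = 3e-04, adjusted p = 0.196 with an estimated correlation), with HSPH1 higher by 0.66 log2 and AHSA1, an activator of HSP90, at 459 ± 15.2 FPKM against 293 ± 6.85. Other transcriptional kinase and elongation genes rose with THZ1 in C312S in 15 of 24 cases and fell in 4 (16 and 4 adjusted over the list alone, median 0.29, camera adjusted p = 0.00986, adjusted p = 0.0151 with an estimated correlation).

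Among lists with no call under YKL 2 µM in WT were the BCL2 family and other cell death genes (11 of 22 higher and 6 lower, median 0.11, limma's camera adjusted p = 0.448), interferon response genes (6 of 20 higher and 8 lower, median -0.06, adjusted p = 0.931) and TFIIH and CDK-activating kinase genes (2 of 10 higher and 4 lower, median -0.09, adjusted p = 0.648). NF-kB target and cytokine genes were higher in 3 of 11 cases and lower in 3 (3 and 2 adjusted over the list alone, median -0.02 and mean -0.04 but upward in limma's camera, adjusted p = 0.931). Heat shock genes were higher in 6 of 19 and lower in 9 (median -0.06 and downward in limma's camera but mean 0.04, adjusted p = 0.684). As markers of other cell types, 3 of 5 blood cell genes were lower (median -0.30, adjusted p = 0.448), and 3 of 6 epithelial and fibroblast genes were higher and 2 lower (median 0.05, adjusted p = 0.778). Between the DMSO groups, 3 of 5 blood cell genes were lower in C312S (median -0.47, limma's camera adjusted p = 0.145), and 5 of 6 epithelial and fibroblast genes were lower and 1 higher (median -0.63, adjusted p = 0.0875). Of the 15 mitochondrially encoded genes, 0 are in the table.

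Across 8218 genes, which are not independent replicates, changes in WT and C312S against separate controls correlated with r = 0.735 for THZ1, 0.067 for THZ531 and 0.114 for YKL 2 µM, the last 2 against the C312S DMSO libraries that stood apart. For the addition of YKL to THZ531 r was 0.486 at 500 nM and 0.686 at 2 µM. In simulated data without effects, DMSO libraries shared within WT gave a covariance of 0.00316 and r = 0.49. That r is no baseline where effects exist. THZ1 and YKL 2 µM correlated with r = 0.504 (covariance 0.111), with 2247 genes called higher in both (1384 if independent) and 2464 lower in both (1497). THZ1 and THZ531 gave r = 0.596 (covariance 0.0812), with 2040 (1045) and 2085 (1021), and YKL 2 µM and THZ531 r = 0.167 (covariance 0.0206), with 1271 (979) and 1240 (983). Shared controls add to each excess.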
